A study of Homo sapiens with 6 samples.

How the data were processed

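RNA from SH-SY5Y cells was sequenced in 3 WT and 3 DNAJC12 knockout libraries. Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was removed with a Ribo-Zero kit and stranded libraries were made with random primers. The submitters' processing notes name cutadapt 3.5, FastQC, Salmon 1.10.0 and DESeq2 1.42.1 and the build GRCh38.p14 (hg38), without giving the role of each. The annotation release is not given in the sources used here, nor is a strand setting.

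The deposited gene table holds estimated counts per gene, rounded to whole numbers and not normalized. From the values, they equal the rounded sums of the transcript files' estimated counts, within 1 read, for 82.8% to 83.7% of the 19584 genes that could be compared. The lowest row total in the table is 10. Per the file headers, each deposited transcript file holds estimated counts and TPM values for 251955 transcripts. The table has 21071 rows, in which 154 genes appear several times with identical counts; 403 repeated rows were removed, leaving 20668 genes. Because Salmon divides reads among similar transcripts, genes with near-identical copies or pseudogenes are uncertain. Gene symbols came from the table and from a RefSeq gene table of GRCh38.p14, which also gave positions for 16137 genes. Transcripts were assigned to genes through GENCODE release 29, which holds 201667 of the transcripts and 94.2% to 94.6% of the reads of each library.

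Library totals ran from 19321842 to 21869659 counts, so that 1 count was 0.0457 to 0.0518 CPM and a floor of 3 counts 0.137 to 0.155 CPM in a library. Intervals of ratios are exact 95% binomial intervals over the summed counts of a group. They and the floor cover counting error only, since reads without molecular identifiers are not independent molecules. The spread between replicates of a genotype exceeded counting noise in every pair (chi-square per gene of 4.30 to 23.0, where sampling alone gives about 1), so that no pair was treated as a single library.

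Genotypes were compared with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr (16403 genes), scaled by TMM and tested with the quasi-likelihood F-test on genotype, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE was taken as the absolute log2 fold change over the square root of F. The 36 gene lists (1292 genes, 1067 tested, 2 of them matched by an older symbol) were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but one. Lists and chromosomes were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The alternatives were an estimated correlation and fry. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment within a list.

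Named genes are DNAJC12, the 15 largest rises and 15 largest falls, the 5 protein-coding genes with the smallest adjusted p, and for each list the 4 members with the smallest adjusted p. The rises and falls were taken from protein-coding genes past the threshold with a symbol, a mean of at least 2 CPM in 1 group and 3 knockout values on one side of the 3 WT values. For lists with fewer than 2 members past the threshold the rule asked for counts alone. H3C6, the single histone gene past it, is named in addition. Some genes named by these rules and 1 of the 36 lists are not reported here; tallies over all lists and named genes include them.

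The other settings were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library size alone, other filters on low counts, a replicate block, each library left out, a fold minimum, protein-coding genes alone, a threshold of 0.01 and gene counts from the transcript files, plain or length-corrected. After the chromosome test had been seen, genes with a mean of at least 4 CPM were scanned in windows of 40 consecutive genes, a segment start was placed at the change point of each shifted chromosome, and a fit without the segments' genes was added. Intervals of segment medians come from 1000 bootstrap samples of genes.

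The tests were tested on simulated data first. In counts simulated for the 16403 genes of the knockout comparison, 67 genes were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Of these edgeR called 58.2%, 62.7% and 89.4%, and 4.11% of its calls were false. The adjusted threshold is stricter when few genes change, so these shares need not hold for the real comparison, which called 4270 genes. The list test called the raised list and 0 others among 30 simulated lists, with either correlation. Genes were simulated independently, so this cannot show how often lists of correlated genes are called falsely.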

Results

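The data were 6 RNA-seq libraries from SH-SY5Y, a human neuroblastoma cell line with properties of sympathetic neuronal precursors. There were 3 libraries from wild-type (WT) cells and 3 from cells in which DNAJC12 had been knocked out with CRISPR/Cas9. DNAJC12 encodes a J-domain co-chaperone of HSP70 that acts on the aromatic amino acid hydroxylases. The series description gives cell invasion as the property under study. RNA was total RNA depleted of ribosomal RNA. The gene table held 20071795, 19321842 and 19418072 counts for WT replicates 1, 2 and 3, and 19845788, 21405492 and 21869659 for knockout replicates 1, 2 and 3. The labels do not say whether the 3 replicates of a genotype were separate cultures or clones, so the p-values measure the spread between these libraries, which may be technical. Fold changes are log2 values for knockout against WT, given ± SE from edgeR's quasi-likelihood fit with n = 3 per group, and adjusted p-values are Benjamini-Hochberg values of that test. Expression levels are CPM after TMM scaling.

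The targeted gene was measured first in every library. DNAJC12 RNA was lower in each knockout library than in each WT library, and part of it remained. Its level was 21.5 ± 1.5 CPM (SD, n = 3) in WT and 5.54 ± 0.601 CPM (SD, n = 3) in the knockout, from 1289 and 342 counts. The change was -1.95 ± 0.13 on the log2 scale (edgeR adjusted p = 1.25e-06), so that 0.257 of the WT level was left (95% exact interval for counting error 0.227 to 0.290). DNAJC12 (ENSG00000108176) lies on chromosome 10 from 67796669 to 67838188 in GRCh38.p14. The position of the guide RNA in the gene is not given in the sources used here. In the transcript files, ENST00000225171 carried most of the estimated reads of DNAJC12, with 448, 408 and 372 in the WT libraries and 108, 105 and 99.8 in the knockout libraries. Within 1 Mb of DNAJC12, 9 other genes were tested and 1 passed the threshold. That gene, RUFY2, changed by 0.44 ± 0.12 (edgeR adjusted p = 0.0218). It lay outside the threshold without WT replicate 1, 2 or 3 or knockout replicate 2, with adjusted p between 0.0533 and 0.0810, and with length-corrected counts from the transcript files (0.331).

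**Figure D1:**
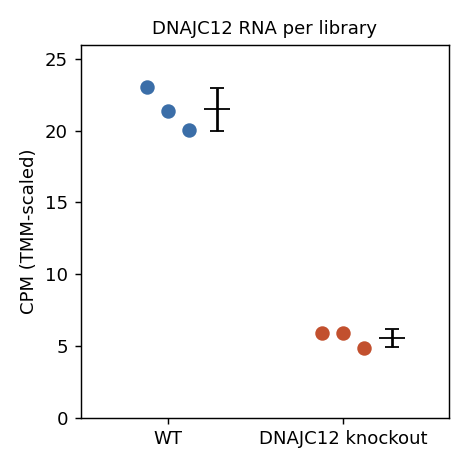
DNAJC12 RNA in CPM (y axis, from 0) for each of the 3 WT and 3 knockout libraries (points), with the group mean and SD beside them. The WT mean is 21.5 CPM and the knockout mean 5.54 CPM, and the groups do not overlap.

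The knockout libraries differed from WT in a large part of the transcriptome. The secreted carboxypeptidase gene CPA4 rose from 1.85 ± 0.122 to 167 ± 12.2 CPM (SD, n = 3), the choline transporter gene SLC5A7 from 3.66 ± 0.218 to 114 ± 8.97 CPM, and the actin-binding smooth muscle gene TAGLN from 8.36 ± 0.875 to 229 ± 24.3 CPM. TFPI2, a protease inhibitor of the extracellular matrix, fell from 1585 ± 322 to 137 ± 24.4 CPM, and the neuronal peptidase gene ECEL1 from 99.5 ± 14.1 to 1.94 ± 0.410 CPM. Of 16403 genes tested, 4270 passed an adjusted p of 0.05, with 2383 higher and 1887 lower in the knockout. Of these, 1044 were higher and 471 lower by at least 2-fold. With library sizes in place of TMM the split was 2055 higher and 2438 lower, because that scaling moved the median gene by -0.06 on the log2 scale. The 3 knockout values lay wholly on one side of the 3 WT values for 6846 genes (41.7%), where chance gives 10%. The first principal component held 68.7% of the variance and separated the genotypes. Correlations of log CPM were at least 0.979 within a genotype and at most 0.945 between genotypes.

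The genes with the smallest p-values were CPA4 (6.49 ± 0.11, edgeR adjusted p = 3.66e-10), LRRC17 (4.75 ± 0.10, adjusted p = 1.18e-09), SLC5A7 (4.96 ± 0.11, adjusted p = 1.28e-09), ARHGAP36 (4.80 ± 0.11, adjusted p = 1.90e-09) and TAGLN (4.78 ± 0.11, adjusted p = 2.11e-09). Several of the genes with the largest rises had no count in the 3 WT libraries together, so that their fold is a lower bound against a floor of 3 counts over the group. By that bound MFAP5, a gene of elastic microfibrils, was at least 101-fold higher, ANOS1 at least 67.8-fold, the AMPA receptor auxiliary subunit gene CACNG2 at least 53-fold, the chromatin remodelling gene DPF3 at least 50.4-fold, the complement factor gene CFI at least 42.6-fold and POU2AF2 at least 42.0-fold higher. For genes with 1 to 3 WT counts the ratio carries a wide counting interval. It was 331 for the procollagen peptidase gene ADAMTS2 (95% exact interval 59.1 to 13125), 213 for the adhesion gene CHL1 (37.9 to 8456), 204 for the ferroxidase gene HEPH (69.4 to 991), 194 for CNTNAP5 (53.3 to 1605), 167 for WSCD2 (45.9 to 1385) and 94.0 for the fucosyltransferase gene FUT9 (25.7 to 781). ADAMTS2 lies in an end part of chromosome 5 in which nearly all genes were higher. The calcium-binding protein gene SCGN (6.23 ± 0.46) was also among the 15 largest rises, as was CPA4. The fitted fold moved by over 1.5 times with a setting for several of these genes, given here as log2 values: without WT replicate 1 for ADAMTS2 (7.92 to 9.80), CHL1 (7.29 to 9.17) and FUT9 (6.31 to 8.98), without WT replicate 2 for CNTNAP5 (7.35 to 10.04) and SCGN (to 7.15), by limma-voom for ADAMTS2 (to 7.26) and CHL1 (to 6.61), and on counts summed from the transcript files for HEPH (7.51 to 10.36). With length-corrected counts from those files it was 6.82 for ADAMTS2 and 10.36 for HEPH.

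The 15 largest falls were led by ECEL1 (-5.68 ± 0.16), FAM124B (-5.08 ± 0.58), PRUNE2 (-4.85 ± 0.32), CA8 (-4.82 ± 0.40) and the homeobox gene HOXC11 (-4.74 ± 0.46). They included PPARGC1A, a coactivator of mitochondrial biogenesis (-4.01 ± 0.42), the diacylglycerol kinase gene DGKB (-3.83 ± 0.16), the respiratory chain isoform gene COX4I2 (-3.80 ± 0.40) and the fatty acid-binding protein gene FABP3 (-3.44 ± 0.47). The others were BSPRY (-4.09 ± 0.25), the amino acid transporter gene SLC38A11 (-3.99 ± 0.38), WFDC1 (-3.57 ± 0.33), TFPI2 (-3.53 ± 0.16), KLHL14 (-3.43 ± 0.45) and FAM162B (-3.40 ± 0.32). With length-corrected counts from the transcript files PRUNE2 fell by less (-2.30, adjusted p = 0.0266), and with counts summed from them so did SLC38A11 (-3.25). FAM124B fell by more without knockout replicate 3 (-6.27) and KLHL14 without knockout replicate 1 (-4.26). Each gene among these rises and falls had an edgeR adjusted p of at most 0.000321.

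**Figure D2:**
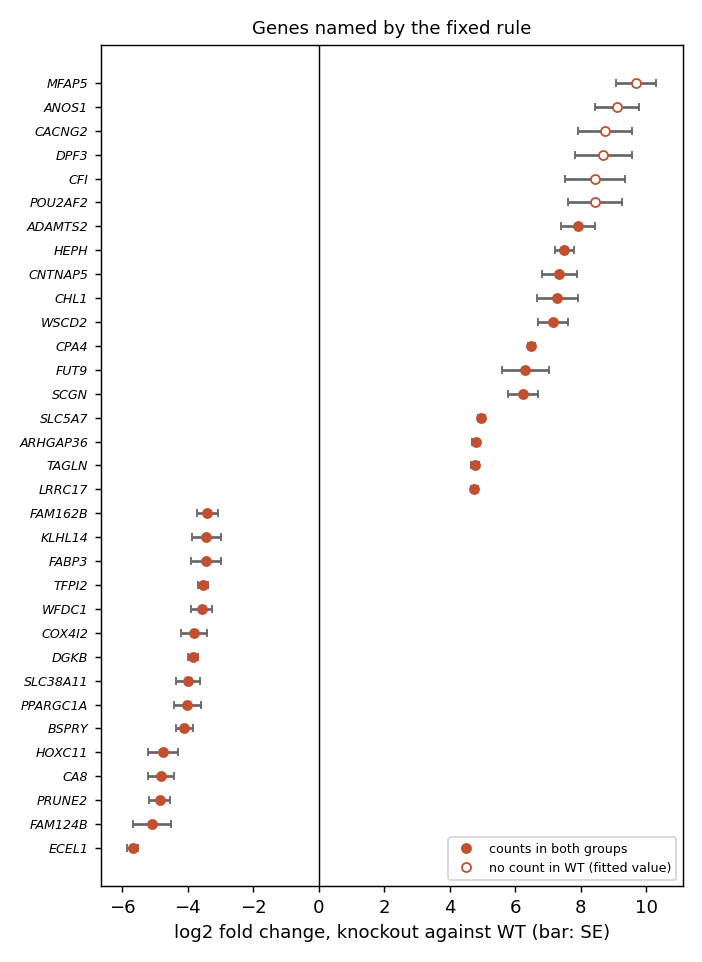
Log2 fold change, knockout against WT, with SE (x axis) for 14 of the 15 largest rises, the 15 largest falls and the genes with the smallest p-values (y axis). Open points are genes with no count in WT, whose fitted value depends on the prior count. CPA4 sits at 6.49 with an SE of 0.11, and ECEL1 at -5.68.

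The comparison was then made over 36 gene lists. Genes of matrix remodelling and of the mesenchymal state, the groups closest to the invasion question, moved in both directions with more rises than falls. Of 26 metalloproteinases, inhibitors and plasminogen system genes tested, 11 rose, 2 fell and 13 did not pass. The metalloproteinase genes ADAMTS5 (3.44 ± 0.11), MMP24 (4.07 ± 0.17) and ADAMTS1 (2.09 ± 0.13) rose, and so did the metalloproteinase inhibitor gene TIMP3 (4.83 ± 0.21). In the list of transition regulators and mesenchymal markers 13 of 21 rose and 3 fell, among them TAGLN, ACTA2 (2.65 ± 0.12), the tropomyosin gene TPM2 (1.81 ± 0.10) and the receptor tyrosine kinase gene AXL (4.98 ± 0.30; 3.04 with length-corrected counts from the transcript files). By camera with a preset correlation these lists were higher than the other genes, with adjusted p = 9.33e-07 and 2.49e-12. The calls were not kept with an estimated correlation (adjusted p = 0.0906 and 0.129 with an estimated correlation). Adjusted over the list alone, 17 and 18 members changed.

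Matrix genes moved in both directions. The collagen genes COL3A1 (1.36 ± 0.05), COL5A1 (1.45 ± 0.07) and COL11A1 (2.44 ± 0.12) rose and COL4A2 fell (-1.22 ± 0.06). Over 24 collagens 6 rose and 11 fell, the median was -0.33 (the same with 2 genes absent from a genotype at their bound) and the mean 0.00229 (0.00567 without those genes), and camera gave an adjusted p of 0.726. Of 41 matrix glycoproteins and proteoglycans 16 rose and 12 fell. The small proteoglycan gene DCN fell (-2.94 ± 0.08), while LTBP1 (2.02 ± 0.09), TGFBI (4.32 ± 0.20; 3.43 with length-corrected counts from the transcript files) and THBS1 (4.94 ± 0.26) rose. The camera adjusted p was 0.0125, and 0.241 with an estimated correlation. Of 19 integrins 5 rose and 4 fell (camera adjusted p = 0.194), with rises in ITGB3 (1.99 ± 0.13), ITGB5 (1.09 ± 0.09), ITGA4 (1.49 ± 0.14) and ITGA5 (1.44 ± 0.14). There were 19 collagens, 29 glycoproteins and proteoglycans and 9 integrins changed when adjusted over the list alone.

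Neuronal genes rose in number. Of 43 synaptic vesicle and neuronal cytoskeleton genes 24 rose, 4 fell and 15 did not pass, with a median of 0.46. The synaptotagmin gene SYT4 rose from 35.7 ± 5.80 to 671 ± 88.9 CPM (SD, n = 3; 4.23 ± 0.13), and NRXN2 (4.50 ± 0.14; 3.81 with length-corrected counts from the transcript files), CPLX2 (4.90 ± 0.19) and ELAVL4 (2.10 ± 0.09) rose as well. CPLX2 lies in the raised part of chromosome 5. Of 41 axon guidance genes 19 rose and 5 fell, with rises in SEMA5A (3.08 ± 0.09), EFNB2 (1.39 ± 0.09), SLIT1 (4.87 ± 0.38; 4.05 with length-corrected counts and 5.53 without WT replicate 2) and UNC5A (1.89 ± 0.12), the last also in that part of chromosome 5. Of 36 ion channels 18 rose and 11 fell, with rises in KCNMA1 (2.02 ± 0.12), the NMDA receptor subunit gene GRIN1 (4.17 ± 0.29) and KCNC1 (4.84 ± 0.34; 5.72 without WT replicate 1). Of 21 neural cadherins and adhesion genes 10 rose and 6 fell: NFASC (3.66 ± 0.16), CDH11 (1.11 ± 0.07) and CHL1 rose, and NRCAM fell (-1.54 ± 0.12). The camera adjusted p-values were 9.89e-11, 4.40e-05, 0.000256 and 0.0127 in this order. With an estimated correlation, adjusted p = 0.0906, 0.241, 0.330 and 0.456. The adhesion list was also not called without knockout replicate 2 (adjusted p = 0.0567). When adjusted over the list alone, 31, 25, 32 and 16 members changed.

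Genes of the noradrenergic phenotype were mixed, and among those of catecholamine handling more fell than rose. In the list of catecholamine and tetrahydrobiopterin genes 4 of 23 rose, 10 fell and 9 did not pass (camera adjusted p = 0.000318; adjusted p = 0.0906 with an estimated correlation). The granule protein genes CHGB (729 ± 62.5 to 156 ± 15.6 CPM; SD, n = 3; -2.23 ± 0.09) and SCG2 (-3.08 ± 0.16) and the vesicle cytochrome gene CYB561 (-1.25 ± 0.07) fell, while the granule protein gene CHGA rose (1.71 ± 0.08), as did SCG3 (1.998 ± 0.152), SCG5 (1.15 ± 0.11) and MAOB (0.81 ± 0.12), these 3 chosen after their values were seen. Also chosen in that way, the enzyme genes DDC (-1.88 ± 0.15), DBH (-0.69 ± 0.09), GCH1 (-0.98 ± 0.10), QDPR (-0.72 ± 0.10) and PCBD1 (-0.40 ± 0.08) fell. So did the transporter genes SLC18A1 (-2.29 ± 0.13) and SLC6A2 (-0.90 ± 0.06). The hydroxylase gene TH was not among the 23 genes tested. Of 27 adrenergic neuroblastoma transcription factors 13 rose and 9 fell. The receptor tyrosine kinase gene ALK (3.31 ± 0.12) and LMO3 (5.28 ± 0.29; 4.08 with length-corrected counts from the transcript files) rose, and INSM2 fell (-1.98 ± 0.10). That list had a camera adjusted p of 0.0405, and 0.241 with an estimated correlation. It was not called without WT replicate 2 or 3 (adjusted p = 0.0598 and 0.0726), with library sizes in place of TMM (0.0580) or among protein-coding genes (0.0539). Of 33 mesenchymal neuroblastoma factors and markers 19 rose and 4 fell (camera adjusted p = 6.14e-07; adjusted p = 0.0906 with an estimated correlation), with rises in the growth factor signalling inhibitor gene SPRY1 (4.33 ± 0.15), AXL and IGFBP5 (91.6 ± 4.84 to 197 ± 8.54 CPM; SD, n = 3) and a fall in TBX18 (-2.38 ± 0.16). Adjusted over the list alone, 14, 23 and 24 members changed.

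Among signalling lists, 14 of 27 TGF-beta, BMP and SMAD genes rose and 2 fell, including TGFB2 (4.94 ± 0.16), TGFBI, BMP7 (1.70 ± 0.13) and INHBA (2.58 ± 0.27). Camera gave an adjusted p of 7.52e-06, and 0.241 with an estimated correlation. The other signalling lists did not pass camera in the main fit. With all libraries the Wnt and NF-kB lists passed by fry (adjusted p = 0.00268 and 0.0147), and the immediate early list passed camera with a replicate block (0.0457). By camera with 1 library left out, the Wnt list passed without WT replicate 2 (adjusted p = 0.0397) and the immediate early list without knockout replicate 1 (0.0106). The NF-kB list passed without WT replicate 3 or knockout replicate 2 (0.0411 and 0.0478). Of 27 Wnt genes 12 rose and 9 fell (camera adjusted p = 0.0952), with rises in FZD7 (1.43 ± 0.08), WNT5A (1.78 ± 0.17), WNT5B (2.49 ± 0.27) and FZD8 (3.58 ± 0.42; 4.33 without WT replicate 2). Of 33 immediate early and MAPK feedback genes 13 rose and 5 fell (adjusted p = 0.181): SPRY1 and FOSL2 (1.26 ± 0.13) rose, and ETV1 (-1.74 ± 0.09) and SPRY4 (-1.14 ± 0.07) fell. Of 21 NF-kB targets and cytokines 4 rose and 2 fell (adjusted p = 0.0975), with rises in the chemokine receptor gene CXCR4 (3.92 ± 0.14) and its ligand gene CXCL12 (4.21 ± 0.34), in CCL2 (1.68 ± 0.18), and a fall in NFKBIE (-1.16 ± 0.15). Of 39 interferon-stimulated and antigen presentation genes 3 rose and 11 fell (adjusted p = 0.260). IFITM2 (1.96 ± 0.11) and IFITM3 (1.98 ± 0.15), near-identical copies between which reads can be split, rose, and OAS3 (-0.68 ± 0.10) fell. OAS3 did not pass on counts from the transcript files (adjusted p = 0.229 summed and 0.226 length-corrected). Adjusted over the list alone, 16, 23, 19, 6 and 14 members of these lists changed.

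No chaperone or stress list passed camera with all libraries and genes. Of 41 DNAJ co-chaperones other than DNAJC12, 3 rose, 4 fell and 34 did not pass (camera adjusted p = 0.597). DNAJB4 (1.77 ± 0.16) rose, and DNAJC22 (-1.39 ± 0.15) and DNAJC1 (-0.77 ± 0.11) fell. Of 38 heat shock genes 4 rose and 5 fell (adjusted p = 0.481; median -0.14, mean 0.08), with rises in HSPB6 (2.90 ± 0.32), CRYAB (3.03 ± 0.41), HSPA12A (0.85 ± 0.11) and BAG2 (0.69 ± 0.11). HSPA12A did not pass on counts summed from the transcript files (adjusted p = 0.0628). Of 38 genes of the unfolded protein and integrated stress response 3 rose and 11 fell (adjusted p = 0.0775; 0.0154 without WT replicate 1, 0.0354 without knockout replicate 2 and 0.0450 without the shifted parts of chromosomes 3 and 5, a setting chosen after seeing the data). DDIT4 (-1.05 ± 0.13), TRIB3 (-0.49 ± 0.08) and SLC7A11 (-1.61 ± 0.27) fell, and CANX rose (0.65 ± 0.11), again in the raised part of chromosome 5. Of 32 p53 targets 6 rose and 5 fell (adjusted p = 0.726), with rises in TP53I3 (1.08 ± 0.13), TNFRSF10B (0.75 ± 0.10) and GADD45A (0.86 ± 0.14) and a fall in GDF15 (-0.81 ± 0.13). Of 28 BCL2 family and caspase genes 2 rose and 5 fell (adjusted p = 0.224). HRK (-1.54 ± 0.22), BIRC5 (-0.35 ± 0.07) and BCL2L12 (-0.48 ± 0.10) fell and CASP8 rose (0.84 ± 0.18), though not on counts from the transcript files (adjusted p = 0.0937 summed and 0.185 length-corrected). In these lists 7, 9, 16, 12 and 7 members changed when adjusted over the list alone.

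Lists of growth and metabolism followed. Of 77 cytosolic ribosomal protein genes 54 rose and 23 did not pass, with a median of 0.25 (camera adjusted p = 1.53e-06; adjusted p = 0.667 with an estimated correlation). RPL26 (0.42 ± 0.05), RPL7 (0.49 ± 0.06), RPL23 (0.40 ± 0.06) and RPL6 (0.36 ± 0.05) rose, and reads of such genes can be shared with processed pseudogenes. Their share of counts was 6.36%, 6.03% and 6.18% in the WT libraries and 7.69%, 6.54% and 7.06% in the knockout libraries. Of 72 nuclear-encoded respiratory chain genes 13 fell and 59 did not pass (camera adjusted p = 0.0373; adjusted p = 0.667 with an estimated correlation). SDHB (-0.40 ± 0.07), UQCRC1 (-0.33 ± 0.06), NDUFB4 (-0.32 ± 0.07) and ATP5F1B (-0.22 ± 0.05) fell. That list was not called without WT replicate 3 (adjusted p = 0.0756) or knockout replicate 3 (adjusted p = 0.0553) or among protein-coding genes (0.0619), and ATP5F1B did not pass without knockout replicate 3 (adjusted p = 0.0730), nor UQCRC1 with length-corrected counts (0.0779). Of 13 mitochondrially encoded messenger RNAs 2 rose and 11 did not pass (camera adjusted p = 0.635), MT-ND5 (0.48 ± 0.10) and MT-CO1 (0.28 ± 0.09). MT-CO1 kept its call without knockout replicate 1 alone, and had adjusted p between 0.0745 and 0.136 without any other library. It did not pass with library sizes in place of TMM (0.0755), by limma-voom (0.0511) or on counts from the transcript files (0.0692 summed and 0.0814 length-corrected).

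Of 50 proliferation and mitosis genes 6 fell and 44 did not pass (camera adjusted p = 0.0773), among them CCND1 (-0.88 ± 0.13), E2F2 (-0.60 ± 0.10), BIRC5 (-0.35 ± 0.07) and CDC20 (-0.31 ± 0.08). CDC20 did not pass without WT replicate 1 or 3 or knockout replicate 3 (adjusted p = 0.0511, 0.0729 and 0.0817). The list itself passed without WT replicate 1 (adjusted p = 0.00341) or knockout replicate 2 (adjusted p = 0.00272). Of 41 histone acetyltransferase and deacetylase genes 8 rose and 3 fell (adjusted p = 0.481), with rises in HDAC9 (1.14 ± 0.08), HDAC7 (0.73 ± 0.09) and CREBBP (0.38 ± 0.08). KAT2B (0.67 ± 0.19) did not pass without WT replicate 1 or 3 or knockout replicate 2 or 3 (adjusted p between 0.0535 and 0.0993) or with length-corrected counts (0.0557). Of 31 cholesterol synthesis genes 4 rose and 6 fell (adjusted p = 0.144; median 0.04, mean -0.08), with falls in STARD4 (-1.81 ± 0.08), SREBF1 (-1.06 ± 0.08) and SCD (-0.56 ± 0.09). Of 36 glycolysis and hypoxia genes 7 rose and 13 fell (adjusted p = 0.493; median -0.14, mean 0.02). ADM (2.28 ± 0.14), EGLN3 (1.39 ± 0.10) and PFKP (0.73 ± 0.08) rose and GPI fell (-0.43 ± 0.06). Of 17 replication-dependent histone genes 1 passed, H3C6 (1.05 ± 0.28), and it did not pass without WT replicate 2 or 3 or knockout replicate 2 (adjusted p = 0.0739, 0.0563 and 0.0501) or with length-corrected counts (0.0539). Of 3 short non-coding RNAs 0 passed by edgeR, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.726 for this list and for the histones). Adjusted over the list alone, 69 ribosomal protein, 10 respiratory chain, 1 mitochondrially encoded, 5 proliferation, 11 acetylation, 13 cholesterol, 23 glycolysis, 0 histone and 0 short RNA genes changed.

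Markers of other cell types were included because cultures can hold them. Of 16 fibroblast markers 8 rose and 5 fell (camera adjusted p = 0.000191; adjusted p = 0.0906 with an estimated correlation). TAGLN, COL3A1 and ACTA2 rose, while DCN fell from 159 ± 7.93 to 20.7 ± 1.23 CPM (SD, n = 3). Of 8 Schwann cell and glial markers 4 fell (camera adjusted p = 0.0194; adjusted p = 0.228 with an estimated correlation): SOX2 (-1.62 ± 0.12), PMP22 (-0.94 ± 0.08), NGFR (-0.63 ± 0.10) and ERBB3 (-0.96 ± 0.31). SOX2 lies in a part of chromosome 3 in which most genes were lower, and without the genes of that part and its counterpart on chromosome 5 the Schwann list was not called (adjusted p = 0.133). It was also not called without WT replicate 2 or 3 or knockout replicate 3 (adjusted p = 0.0650, 0.0686 and 0.0953). ERBB3 passed without knockout replicate 1, and had adjusted p between 0.0535 and 0.193 without any other library. On counts from the transcript files it was -2.55 (summed, adjusted p = 0.0523) and -1.92 (length-corrected, 0.0968). Of 9 epithelial markers the keratin genes KRT18 (2.98 ± 0.09) and KRT8 (3.26 ± 0.17; 1.93 with length-corrected counts from the transcript files) rose and CLDN4 fell (-1.72 ± 0.17; camera adjusted p = 0.0773, 0.00360 at a CPM of at least 1 in 3 samples and 0.0329 without knockout replicate 2). Of 9 leukocyte and endothelial markers 2 rose and 1 fell (camera adjusted p = 0.759; median -0.02, the same with EMCN at its bound; mean 0.75, but 0.41 with EMCN at its bound and -0.06 without it). EMCN, with no WT count, was at least 17.8-fold higher and CD68 rose (0.95 ± 0.17). EGFL7 fell (-0.44 ± 0.13) and did not pass without WT replicate 1 or 3 or knockout replicate 2 or 3 (adjusted p between 0.0579 and 0.111) or on counts from the transcript files (0.0505 summed and 0.0650 length-corrected). In the 4 marker lists 13, 5, 4 and 3 members changed when adjusted over the list alone.

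**Figure D3:**
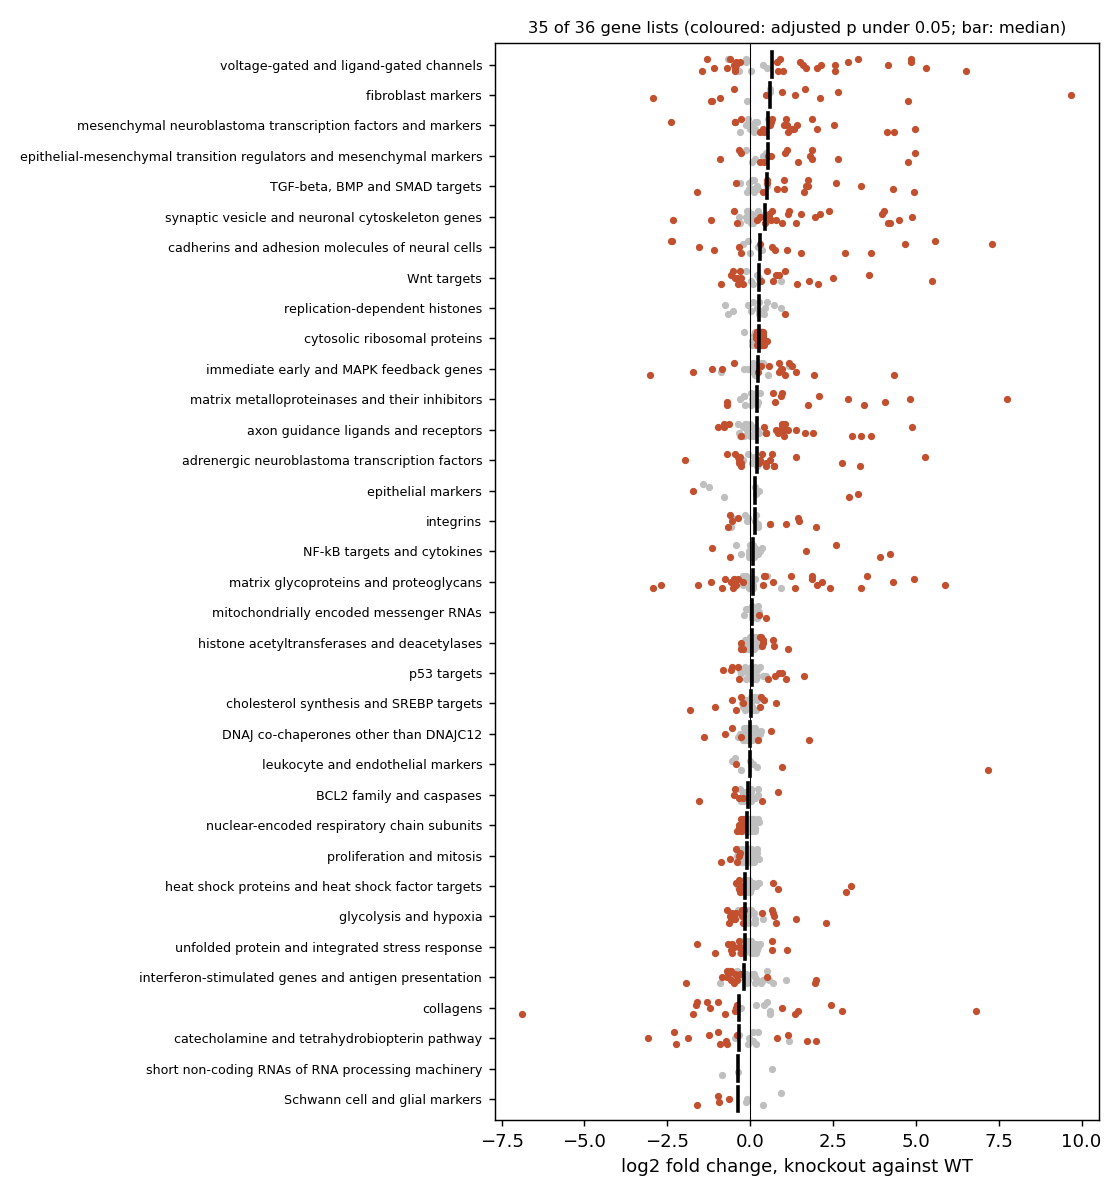
Log2 fold change, knockout against WT (x axis), of each tested member (points) of 35 of the 36 lists (y axis, ordered by median); coloured points passed the adjusted p threshold and black bars are list medians. The channel list has the highest median, 0.66, and most lists hold members on both sides of 0.

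Over the 36 lists, camera with the preset correlation called 16, of which 13 were higher and 3 lower, and 0 with an estimated correlation per list, where 7 lists had an unadjusted p under 0.05. The smallest adjusted p with an estimated correlation was 0.0906, held by 5 lists. The self-contained test fry, which asks whether a list's genes move one way without comparing them with other genes, called 22. These were the 16 lists called by camera and 6 more. By fry the adjusted p was 0.00476 each for integrins, epithelial markers and the BCL2 family and caspases. It was 0.0236 for histone acetyltransferases and deacetylases, 0.00268 for Wnt targets and 0.0147 for NF-kB targets.

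Whole chromosomes were compared next. By camera 0 of the chromosomes passed; chromosome 5 came nearest (adjusted p = 0.214, median 0.12) and alone had an unadjusted p under 0.05. Without knockout replicate 1 chromosome 5 passed (adjusted p = 0.0365). A scan in windows of 40 consecutive genes, added after this result was seen, placed the difference at the ends of 2 chromosomes. From CCNG1 (163437571 on chromosome 5, GRCh38.p14) to the last gene of the long arm, 90 scanned genes had a median of 0.67 (95% bootstrap interval 0.59 to 0.73), a ratio of 1.59, and 98.9% of them were higher in the knockout. From SOX2 (181711925 on chromosome 3) to the last gene of the long arm, 79 scanned genes had a median of -0.46 (95% bootstrap interval -0.55 to -0.39), a ratio of 0.725, and 94.9% of them were lower. Of all windows, 5 lay beyond every one of 1000 permuted gene orders, whose largest median was 0.28, and all 5 lay in these parts or across their start. The largest of the other windows was 0.20. These parts held 160 of the 4270 changed genes (3.75%). In the raised part of chromosome 5, ADAMTS2 (7.92), CPLX2 (4.90) and UNC5A (1.89) rose by more than its median of 0.67.

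**Figure D4:**
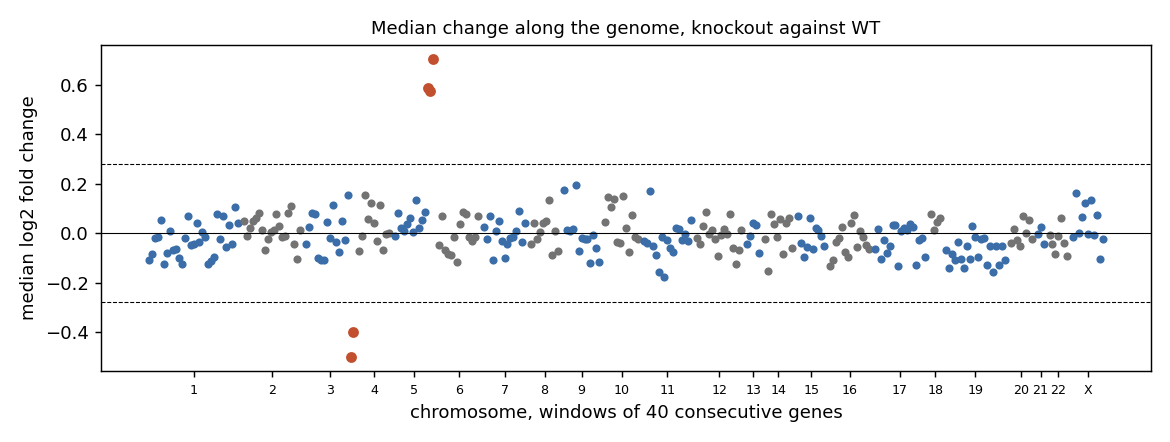
Median log2 fold change, knockout against WT (y axis), of windows of up to 40 consecutive genes along each chromosome (x axis). Dashed lines mark 0.28 and -0.28, the largest window median in 1000 permuted gene orders; the larger coloured points at the ends of chromosomes 3 and 5 are the 5 beyond them.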

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

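The fall in DNAJC12 kept its direction and its call in all 20 settings run, with log2 fold changes from -2.01 to -1.87. The count of changed genes, 4270, stayed within 1.5 times in most settings and ran from 2966 to 4772 with 1 library left out, lowest without knockout replicate 3. It was 2469 against a 1.2-fold minimum (glmTreat), 2663 at a threshold of 0.01 and 1515 with a 2-fold minimum, as stricter criteria require. It was 2828 with length-corrected counts from the transcript files, for which the cause was not tested. DESeq2 gave 4323 and limma-voom 4346, sharing 4061 and 4209 genes with the 4270, each in the same direction. The number of lists called fell from 16 to 0 with an estimated correlation and ran from 14 to 19 with 1 library left out. A higher correlation cannot be the cause of that fall for every list. The estimates for metalloproteinases (0.00413), catecholamine genes (-0.00269) and fibroblast markers (-0.0428) lay below the preset 0.01. Those of other lists, such as ribosomal protein genes (0.658), lay above it. What else changed the calls was not tested. The number of chromosomes called ran from 0 to 1, being 1 without knockout replicate 1. Replicate numbers did not pair the libraries: libraries with the same number had correlated deviations of 0.06, -0.03 and -0.07, and WT replicate 3 went best with knockout replicate 2. With a replicate block 4565 genes, 17 lists and 0 chromosomes were called; the adhesion list lost its call and the proliferation and immediate early lists gained one (adjusted p = 0.0531, 0.0449 and 0.0457). The direction of 2 uncalled lists reversed: collagens under the block (adjusted p = 0.972) and leukocyte and endothelial markers at a CPM of at least 1 in 3 samples (adjusted p = 0.903). For 182 named genes there were 3629 results under other settings, of which 3493 kept direction and call, 129 lost the call and 5 gained it. CHRM3 alone reversed, to -0.85 with counts summed from the transcript files (edgeR adjusted p = 0.431) and -0.47 with length correction (0.654), neither past the threshold. The cause was not tested. Without the 3q and 5q segments, a setting chosen after seeing the data, 4064 genes and 16 lists were called, the unfolded protein list gaining its call (adjusted p = 0.0450) and the Schwann list losing it. In simulated counts with few changed genes the test called 58.2% of 1.5-fold changes, a share that need not hold here. Genes that did not pass are not shown to be unchanged.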

Other observations

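All tests and gene groups in this part were chosen, or their predictions written, after the results they bear on were seen.

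Genes of acetylcholine signalling were grouped because several were seen to change, so that no test of the groups is given. Of 8 genes for acetylcholine synthesis, packaging, uptake, breakdown and muscarinic receptors, 5 rose and 0 fell. The choline transporter gene SLC5A7 (4.96 ± 0.11), the vesicular acetylcholine transporter gene SLC18A3 (1.74 ± 0.18), CHRM2 (3.49 ± 0.09), CHRM3 (0.70 ± 0.13) and CHRM4 (2.72 ± 0.64) passed the edgeR threshold, and CHAT had a value of 1.86 ± 0.63 (adjusted p = 0.0536; between 0.0163 and 0.0461 in 5 other settings, with a value of 2.97 without WT replicate 1). On counts summed from the transcript files CHRM3 did not pass and its value was negative (-0.85, edgeR adjusted p = 0.431). Of 8 nicotinic receptor subunit genes 0 rose and 5 fell, including CHRNA3 (-0.69 ± 0.06), CHRNA5 (-0.50 ± 0.11) and CHRNB4 (-0.43 ± 0.08), which are neighbours on chromosome 15.

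The HOXD genes on chromosome 2 were higher together. Of 8 tested 7 rose and 0 fell, against 0 risen and 2 fallen of 7 HOXC genes. HOXD8 rose from 10.1 ± 0.584 to 42.0 ± 1.08 CPM and HOXD9 from 11.4 ± 1.1 to 47.8 ± 1.03 CPM (SD, n = 3), and HOXD10 by 4.01 ± 0.32, while HOXC10 (-2.47 ± 0.29) and HOXC11 (-4.74 ± 0.46) fell. HOXD1 did not pass without WT replicate 3 or knockout replicate 1 (adjusted p = 0.0540 and 0.0515). They too were singled out after this was seen, and no test of the group is given. In all, 54 genes with at most 3 counts over the WT libraries were called, 22 of them with 0, and 11 genes with at most 3 counts over the knockout libraries, 3 of them with 0.

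The shift of the ends of 3q and 5q was weighed against chance and copy number. Permuted gene orders gave window medians of at most 0.28, below each of the 5 shifted windows, which argues against a chance order of genes. A different copy number would move most genes of a segment by a like ratio whatever their level. The medians of genes of low, middle and high expression were 0.72, 0.68 and 0.60 on 5q and -0.56, -0.43 and -0.38 on 3q, the smallest shift being 0.38, and the last 20 genes of each arm had medians of 0.68 and -0.43. The starting copy numbers are not given in the sources used here, and the sizes of the shifts single out no copy change. On the log2 scale a change from 2 copies to 3 gives 0.58, just below the 5q interval of 0.59 to 0.73. A change from 2 copies to 1 gives -1 and one from 3 to 2 gives -0.58, both outside the 3q interval of -0.55 to -0.39, while one from 4 to 3 gives -0.42, inside it. These intervals resample genes as if independent and leave out the spread between libraries. The segment starts were also chosen on the same values. Changes that lie just outside, 0.58 on 5q and -0.58 on 3q, are therefore not excluded. A gain of the end of 5q and a loss of the end of 3q in the knockout cells are a candidate explanation, without any measurement of DNA here. Each knockout library carried both shifts, by 0.65 to 0.66 on 5q and by -0.40 to -0.52 on 3q, the smallest shift being 0.40, and no WT library moved by more than 0.03, so the 3 knockout libraries may share one cell of origin.

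The number of changed genes was weighed against these segments, depth and grouping. The segments held 160 of the 4270 changed genes, so most calls lay elsewhere in the genome; an effect of the segments' genes on other genes was not tested and stays open. Library totals differed little, and after every library was thinned to 19321842 counts 4207 genes were called, so unequal sequencing depth does not account for the 4270. The 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 4270 genes and the highest of the others 0, with 1 of 10 as large. The others hold both genotypes in each group, which widens the spread within groups, so their 0 is no measure of chance. The labels name a clone for 0 of the 6 libraries, so differences between cloned cells that have nothing to do with DNAJC12 cannot be told apart from its loss, and both remain open for every gene group described. The same limit on splits holds for the 16 lists called, where 1 of 10 splits was as large and the others called 7 to 12. The preset correlation thus called lists in splits that mix the genotypes and in which 0 genes passed. Each such split still holds unequal numbers of knockout libraries in its groups, so part of the genotype difference remains in it. The splits therefore cannot show how often the preset correlation calls lists falsely. Its p-values alone are still not taken to tie a list to genotype, since 0 lists were called with an estimated correlation. For the 0 chromosomes called the splits decide nothing, since no split can call fewer and all 10 of 10 were as large; the highest of the others called 9.

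The higher contractile and matrix genes were weighed against fibroblasts in the knockout cultures. Such cells would raise their abundant transcripts together. Of the 16 fibroblast markers 8 rose and 5 fell. Those that rose included MFAP5, from 0 to 314 counts over a group, and COL1A1, from 51.8 ± 1.51 to 101 ± 11.1 CPM (SD, n = 3). DCN, LUM (-1.17 ± 0.07), FBLN1 (-0.48 ± 0.06), DPT (-1.16 ± 0.16) and S100A4 (-0.91 ± 0.17) fell. DCN, LUM and FBLN1 stood at 159, 97.4 and 405 CPM in WT, so their fall cannot exclude a small added share of fibroblasts. COL1A2 went from 1.94 ± 0.728 to 2.95 ± 0.857 CPM (SD, n = 3) and did not pass (edgeR adjusted p = 0.232). COL3A1 went from 641 ± 20.4 to 1642 ± 29.4 CPM. Fibroblasts that make both collagens in like amounts would not leave that difference. For the rise of COL3A1 these values argue against such fibroblasts as the main source. For the other genes, added fibroblasts and a change within the neuroblastoma cells, by DNAJC12 loss or by clone, both remain open and were not tested further.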
